A study of Mus musculus with 20 samples.

How the data were processed

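RNA was measured in 20 mouse intestinal libraries: 7 from Apc Min mice given a control treatment, 6 from Apc Min mice given DM-aKG and 7 from untreated WT mice. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was purified with a Qiagen kit and libraries were made with an Illumina TruSeq kit from total RNA. The sample titles name tissue and other label fields name intestinal organoids in culture, and the labels do not resolve this. Transcripts of other cell types, given in the Results, argue against organoids of epithelium alone.

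The values used were a table of 24795 genes by 20 libraries that the authors deposited, read here as RPKM (reads per kilobase of gene, divided by the mapped reads of the library). The unit was inferred from the values, which are not whole, sum to 277634 to 369409 per library and step by an amount that depends on the gene. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.0.4 and Partek were used with the mm10 mouse genome. Their roles and order, the gene annotation and the strand setting of the counting are not given in the sources used here. Because RPKM divides by the library total, a large change in a few abundant genes moves all others: the 10 most abundant genes held 6.6 to 13.8% of the summed RPKM. Of the genes, 4272 were at 0 in every library, 26 had names turned into dates by a spreadsheet, 2 of them repeated, and 24228 matched a GENCODE M21 symbol, whose mm10 positions are given. Mitochondrially encoded genes were not analysed here.

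Depth was estimated from the step between low values. Assuming whole reads, 65.9 to 72.3% of the values of 744 to 906 genes per library fell within 0.1 read of a whole number up to 8 reads, where evenly spread values would give 20%. The estimate was 21.3 to 29.3 M reads per library. Too few values came out whole to recover counts, so no count test was run. The share of Rn45s in the reads, 1.4 to 8.53%, assumes a length of 13 kb. No pair of libraries held identical values, and Pearson correlations between libraries over genes were 0.9155 to 0.9961.

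The tests chosen before the data were examined covered counts and normalized values, and the branch for normalized values applied. Genes with at least 1 RPKM in at least 6 libraries were kept (12433 genes), and log2(RPKM + 1) was fitted for all 20 libraries and 3 groups with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings, statmod 1.5.0). Calls are at a Benjamini-Hochberg adjusted p under 0.05 from limma, 2-sided. Tests of single library measures are 2-sided exact permutation tests, whose smallest p is 0.000583 for 7 against 7 and for 6 against 7 libraries. Gene lists, 40 in all and fixed before the data were examined, were tested where at least 5 members were measured, with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a comparison. No list passed camera with an estimated correlation in any of the 3 comparisons. Some lists share members: Axin2, Lgr5, Ascl2, Tnfrsf19, Cd44 and Sox9 stand in both the Wnt target and the stem cell list.

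Named genes followed a rule fixed in advance. They passed the threshold, had a mean log2(RPKM + 1) of at least 2 and had the median of one group outside the whole range of the other. The 10 with the largest change each way were taken for the treatment and 8 each way for the other comparisons, leaving out predicted genes and receptor or antibody segments. Up to 4 members of each list with the smallest p and 17 fixed genes were added. Some genes picked by the rule are not reported here. Single members that moved against their list (Cdx1, Pigr, Mxi1, Apoa4, Galnt12, Got2, Aco1 and Oasl1 among them) were named after their values were seen.

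The limma step was tested on simulated data with changes planted in 67, 67 and 66 of 12433 genes at log2 sizes of 0.5, 1 and 2. For DM-aKG against control it recovered 49.3, 95.5 and 98.5% of them with 14 false calls in 176. For control Apc Min against WT it recovered 50.7, 89.6 and 100% with 4 false calls in 164, and for DM-aKG Apc Min against WT 49.3, 91 and 93.9% with 6 false calls in 162. The simulated noise was normal and independent between genes. Rises and falls were planted in equal number, only in genes with a mean log2(RPKM + 1) of at least 2. Far fewer genes changed than were called in the data, so these rates may not hold there. Alternatives varied the normalization, the filter, the pseudocount, the weights, the libraries in the fit and a fold threshold, left out each library in turn, and used the replicate number as a block, which gave 758 genes higher and 3603 lower with DM-aKG. Another 4 were added after the data were seen: median-of-ratios scaling of RPKM, replicates 1 to 4 and 5 to 7 as a factor, replicates 1 to 4 only, and the mean of the smooth muscle genes as a covariate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depth estimate and figures.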

Results

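RNA sequencing of mouse intestinal material gave 20 libraries in 3 groups: 7 from Apc Min mice given a control treatment, 6 from Apc Min mice given DM-aKG, and 7 from wild-type (WT) mice that the labels list as untreated. Apc Min mice carry a nonsense mutation in Apc, a scaffold of the complex that degrades beta-catenin, and develop intestinal adenomas. DM-aKG is dimethyl alpha-ketoglutarate, a cell-permeable ester of alpha-ketoglutarate, which is an intermediate of the TCA cycle and a cofactor of 2-oxoglutarate-dependent dioxygenases. The sample titles name tissue, while other label fields name organoids grown in culture. Transcripts of smooth muscle, plasma cells and immune cells were measured in every library: Myh11, a smooth muscle myosin, lay between 36.8 and 212.6 RPKM, Jchain, made by plasma cells, between 34.4 and 689.1 RPKM, and the pan-leukocyte gene Ptprc between 1.01 and 9.93 RPKM. Cultures of epithelium alone would lack these cells, so the values argue against such organoids as the source of the 20 libraries. Values are RPKM means ± SD over the 7 control, 6 DM-aKG or 7 WT libraries unless stated, and log2 changes are differences of log2(RPKM + 1), which understate the change of genes with low values. For gene lists, the count of members adjusted over the list alone is given where it differs from that over all genes tested. Where a list passed camera, its adjusted p stands first with the preset and then with an estimated correlation. Camera compares a list with the other genes, so a list can pass with few members called. The median log2 change of all tested genes was -0.142 for DM-aKG over control and 0.199 for control Apc Min over WT. For DM-aKG Apc Min over WT it was 0.0528. Ranges over alternatives cover every other processing tried, leaving out single libraries included. The step between low values placed the depth at 21.3 to 29.3 M reads per library. The difference in depth between DM-aKG (26.93 ± 0.344 M, n = 6) and control libraries (26.76 ± 2.52 M, n = 7) did not pass (exact p = 0.976). Genes at 1 RPKM or more numbered 11650 ± 136 in DM-aKG and 12030 ± 212 in control libraries (exact p = 0.00466). In WT libraries they numbered 11420 ± 247 (exact p = 0.000583 against control). The 10 most abundant genes held 11.93 ± 1.28% of the summed RPKM in DM-aKG and 9.271 ± 2.39% in control libraries (exact p = 0.0402). The nuclear ribosomal transcript Rn45s lay between 3835.6 and 6557.9 RPKM in the 12 libraries of replicates 1 to 4 and between 1078.1 and 3620.9 RPKM in the 8 libraries of replicates 5 to 7, a division that was chosen after these values were seen and so was not tested on them. Values within these sets, each of which holds all 3 groups, stand beside the pooled ones for the leading results. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries.

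The treated against the control Apc Min libraries address whether alpha-ketoglutarate changes Wnt signalling and differentiation, the question in the series title. In this comparison control values stand first. Wnt target genes fell with DM-aKG as a group: of 23 measured, 22 fell and 1 rose, the intestinal transcription factor Cdx1 (the same counts adjusted over the list alone), with a median log2 change of -1.49 (camera adjusted p = 1.31e-09 and 0.26). Notum, a secreted Wnt inhibitor induced by Wnt itself, fell from 72.6 ± 37.9 to 8.75 ± 13.7 RPKM, against 0.128 ± 0.0459 RPKM in WT. It was 35.9 RPKM in DM-aKG replicate 2 and 0.239 to 7.39 RPKM in the other DM-aKG libraries. Wif1, another secreted Wnt antagonist, fell from 72.8 ± 22.4 to 8.05 ± 10.9 RPKM. Lef1, a transcription factor of the pathway, fell from 3.78 ± 1.16 to 0.394 ± 0.487 RPKM, and the feedback inhibitor Nkd1 from 53.2 ± 12.1 to 9.49 ± 9.13 RPKM. The median change of the list was -1.32 within replicates 1 to 4 and -2.19 within replicates 5 to 7.

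Apc itself, on chromosome 18 (34220924 to 34322552, mm10, forward strand, protein coding), stood at 14.5 ± 4.1 RPKM in control and 13.8 ± 1.71 RPKM in DM-aKG libraries (log2 change -0.03 ± 0.17 SE, adjusted p = 0.912), and since the Min allele is a point mutation its level does not check the labels. Axin2, a direct target and feedback inhibitor, fell by 1.86 on the log2 scale (SE 0.23, adjusted p = 4.47e-06), and Notum, on chromosome 11 (120653788 to 120661175, reverse strand), fell by 3.80 (SE 0.56, adjusted p = 3.9e-05). The stem cell receptor Lgr5 fell from 13.5 ± 8.88 to 3.74 ± 2.6 RPKM, the stem cell factor Ascl2 from 2.92 ± 1.17 to 0.848 ± 0.405 RPKM and Myc from 13.1 ± 3.61 to 7.08 ± 1.14 RPKM. Of 20 intestinal stem cell genes 11 fell and none rose (14 lower and 1 higher adjusted over the list alone, median -1.05, camera adjusted p = 0.00146 and 0.629). Mex3a, an RNA-binding protein of stem cells, and Igfbp4, which binds insulin-like growth factors, were among them, with Igfbp4 at 120.4 ± 20.3 against 39.9 ± 11.5 RPKM. Olfm4, another stem cell marker, did not pass (27.2 ± 31.6 in control, 47.5 ± 30.5 RPKM in DM-aKG, adjusted p = 0.181). Without the libraries of replicates 5 to 7, Lgr5 (adjusted p = 0.276, over alternatives 0.00075 to 0.276) and Myc (0.112, 0.00095 to 0.118) were no longer called. Olfm4 was called higher (0.00747, 0.00747 to 0.613). A difference between the sets of replicates did not pass for Lgr5 (interaction adjusted p = 0.372), Myc (0.459) or Olfm4 (0.28).

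**Figure D1:**
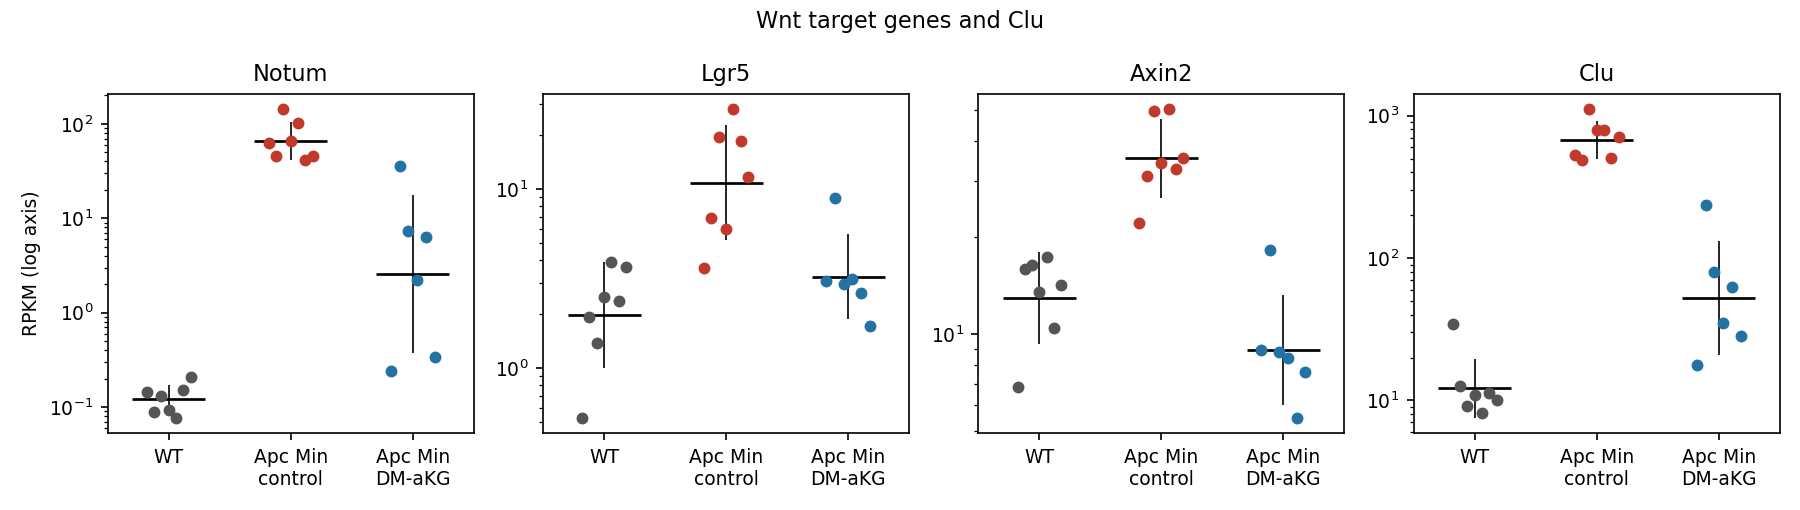
RPKM of Notum, Lgr5, Axin2 and Clu in each library on log axes, by group, where each point is a library, the horizontal line the geometric mean and the vertical line 1 SD on the log2 scale. The 7 control libraries lie above the WT libraries for Notum and Clu, and 5 of the 6 DM-aKG libraries lie below 8 RPKM for Notum.

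The largest falls with DM-aKG were in genes almost silent in WT. Wfdc18, a small secreted whey acidic protein on chromosome 11 (83709015 to 83711348), fell from 192 ± 76.5 to 11.2 ± 15.7 RPKM, and Ctse, an aspartic protease of gastric epithelium, from 113 ± 34.9 to 12.2 ± 21 RPKM. DM-aKG replicate 2 raised both treated means, at 41.6 RPKM for Wfdc18 and 54.4 RPKM for Ctse. The other DM-aKG libraries lay at 0 to 13.9 RPKM for Wfdc18 and 0.263 to 9.95 RPKM for Ctse. The complement factor Cfi, the amino acid transporter Slc38a4, the gastrokine Gkn3, the placental hormone Prl2c2, Bpifb5 and the retinol-binding protein receptor Stra6 had log2 changes of -3.68 to -4.24. Genes of fetal and regenerating epithelium fell as well, 11 of 15 with none rising (13 lower adjusted over the list alone, median -1.14, camera adjusted p = 8.2e-06 and 0.26). Clu, the marker of revival stem cells, on chromosome 14 (65968483 to 65981547), fell from 705 ± 224 to 76.4 ± 80.9 RPKM, the annexin Anxa3 from 19.998 ± 4.07 to 4.88 ± 1.35 RPKM and the interleukin-1 antagonist Il1rn from 23.9 ± 5.69 to 3.32 ± 2.63 RPKM. Among 18 antimicrobial and inflammatory genes 7 fell and 1 rose, the immunoglobulin transporter Pigr (9 lower adjusted over the list alone, camera adjusted p = 0.288), led by Duoxa2, the maturation factor of an oxidase of the mucosa, and by the lipocalin Lcn2 (81.2 ± 25.7 to 20.2 ± 27.1 RPKM). Of 15 pan-epithelial genes 8 fell and 1 rose, the microvillus gene Vil1 (camera adjusted p = 0.42). The tight junction gene Cldn4 and the keratin Krt18 led the falls, while Epcam, the common epithelial adhesion molecule, stood at 800 ± 90.2 in control and 654 ± 77.3 RPKM in DM-aKG libraries (adjusted p = 0.0447). The Epcam call was lost without control replicate 1, 2, 3, 4 or 7, DM-aKG replicate 2, 3, 4 or 5, or WT replicate 3 or 6 (adjusted p 0.0531 to 0.125). It was also lost with only the 2 groups compared (0.0832), with rRNA and haemoglobin left out of the scaling (0.0719), with the smooth muscle covariate (0.166) and after median-of-ratios scaling (0.495, over alternatives 0.0045 to 0.495).

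Genes of absorptive enterocytes rose, 10 of 24 with none falling (median 0.548, 10 also adjusted over the list alone, camera adjusted p = 2.85e-08 and 0.26). Their median was 0.219 within replicates 1 to 4 and 0.992 within replicates 5 to 7, a difference that was not tested for the list. Of 10 genes of the proximal small intestine 3 fell and none rose (4 fell adjusted over the list alone, camera adjusted p = 0.817), and their median was -0.519 and 1.51 within the same sets, again not tested. The chloride exchanger Slc26a3 rose from 34.04 ± 5.45 to 55.9 ± 15 RPKM, the brush border maltase Mgam from 260 ± 56.3 to 371 ± 45.3 RPKM and Apob, the structural protein of chylomicrons, from 322 ± 64.6 to 502 ± 136 RPKM. Other markers of mature enterocytes did not pass the test: Krt20 (530 ± 135 and 456 ± 167 RPKM in control and DM-aKG), Alpi (133 ± 67.3 and 167 ± 97 RPKM) and Fabp2 (2276 ± 1820 and 3636 ± 1650 RPKM). Fabp2 was called higher without control replicate 1 (adjusted p = 0.0395) or control replicate 4 (0.0372, over alternatives 0.0372 to 0.974). Enteroendocrine genes rose in 5 of 14 with none falling (median 0.404, camera adjusted p = 6.45e-06 and 0.26). These included the hormone Sst, at 17.96 ± 5.21 against 34.7 ± 5.96 RPKM, and the granins Chga and Chgb, with Chga at 9.68 ± 2.46 against 19.4 ± 7.24 RPKM. Of 15 goblet cell genes 5 fell and 1 rose, the mucus protease Clca1 (camera adjusted p = 0.499). The mucin Muc2 did not pass (242 ± 72.6 and 213 ± 37 RPKM), while Retnlb, a secreted resistin-like protein, fell from 5.71 ± 2.08 to 2.04 ± 1.84 RPKM. In the tuft cell list 1 of 10 genes fell, the actin-binding gene Avil (27.8 ± 5.68 to 4.39 ± 3.23 RPKM), and the tuft marker Dclk1 stayed at 1.06 ± 0.425 and 1.05 ± 0.646 RPKM. With replicates 1 to 4 only, 3 of these genes lost their call. Apob went from 0.62 to 0.35 (adjusted p = 0.0761, over alternatives 0.00167 to 0.0958, the highest with array weights at 0.33). Retnlb went from -1.34 to -0.86 (0.143, 0.000712 to 0.143) and Chga from 0.89 to 1.10 (0.0504, 0.00336 to 0.0903, the highest with the smooth muscle covariate). An interaction with the replicate sets did not pass for Apob (adjusted p = 0.365), Retnlb (0.39) or Chga (0.71).

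Paneth cell genes gave the largest rises. Of 13 tested 8 rose and 3 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.00382 and 0.629). The antimicrobial enzyme Lyz1 rose from 667 ± 712 to 2083 ± 784 RPKM and the alpha-defensin Defa22 from 585 ± 802 to 2914 ± 1310 RPKM, and the 10 largest rises past the naming rule were the defensin-like AY761184, on chromosome 8 (21702519 to 21703645), and 9 alpha-defensins led by Defa6 and Defa5. Those that fell were Habp2, Pla2g2a, a phospholipase that modifies adenoma number in Apc Min mice, and Mmp7, a protease and Wnt target, with Pla2g2a at 296 ± 152 against 63.1 ± 76.5 RPKM. Pla2g2a was 217 RPKM in DM-aKG replicate 2 and 17.5 to 56.1 RPKM in the other DM-aKG libraries. Alpha-defensins are near-identical copies among which reads may be shared, so their sum over 27 genes is the safer value: 6404 ± 8651 RPKM in control (n = 7) and 27730 ± 12370 RPKM in DM-aKG libraries (n = 6, exact permutation p = 0.00583). The difference was not alike in the sets of libraries parted by Rn45s. In replicates 1 to 4 the sum was 990.6 ± 97.24 in control and 33130 ± 10640 in DM-aKG libraries (n = 4 each, exact p = 0.0286, the smallest possible). In replicates 5 to 7 it was 13620 ± 9365 (n = 3) and 16930 ± 8673 (n = 2, exact p = 0.8). The smallest possible p there is 0.1, so that test could not pass. The difference between the sets passed the test for Defa5 (interaction adjusted p = 0.0187) and Defa22 (0.0207) but not for Lyz1 (0.105). The call of Defa6 was lost when any of 8 single libraries was left out, control replicates 1 to 4 and DM-aKG replicates 1, 3, 4 and 5 (adjusted p 0.0519 to 0.0709, over alternatives 0.000784 to 0.151).

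**Figure D2:**
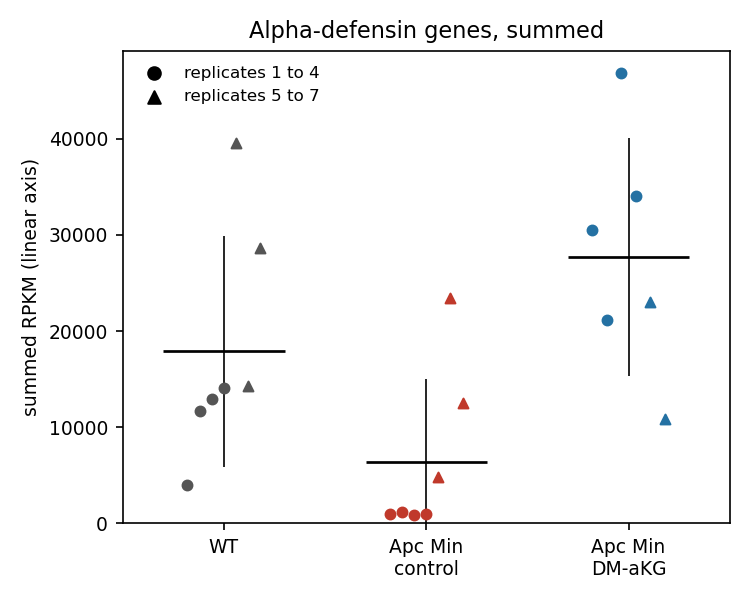
Summed RPKM of the 27 alpha-defensin genes in each library on a linear axis that starts at 0, by group, with the mean as a horizontal line and 1 SD as a vertical line that ends at 0 where it would pass below. Circles are replicates 1 to 4 and triangles replicates 5 to 7, and the 4 control circles lie between 887.56 and 1118.5 RPKM.

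Metabolic groups moved in both directions. Hypoxia-inducible factor targets fell in 14 of 20 with none rising (15 lower adjusted over the list alone, median -0.60, camera adjusted p = 0.00353 and 0.409): the carbonic anhydrase Car9 went from 34.7 ± 7.22 to 12.2 ± 2.94 RPKM and the glucose transporter Slc2a1 from 48.9 ± 16.4 to 12.7 ± 10.1 RPKM. Cholesterol synthesis genes fell in 15 of 23 with none rising (16 adjusted over the list alone, camera adjusted p = 0.0326 and 0.775, 8 lower after quantile normalization), among them the farnesyl diphosphate synthase Fdps. Genes of fatty acid oxidation rose in 6 of 21 with none falling (3 higher adjusted over the list alone, camera adjusted p = 5.61e-06 and 0.409), including the peroxisomal enzyme Ehhadh. In the TCA cycle and glutamine list 3 of 31 rose, among them Aco1 and the alanine transaminase Gpt, which makes or uses alpha-ketoglutarate, and 1 fell, the transaminase Got2 (3 and 0 adjusted over the list alone, camera adjusted p = 4.49e-05 and 0.26). Of 21 ATF4 and amino acid response genes 9 fell and none rose (10 adjusted over the list alone, camera adjusted p = 0.18). Phgdh, the first enzyme of serine synthesis, stood at 7.26 ± 2.09 against 2.39 ± 0.803 RPKM and the proline synthesis gene Pycr1 at 4.33 ± 1.74 against 0.836 ± 0.44 RPKM. Among 27 dioxygenases that use 2-oxoglutarate 7 fell and none rose (median -0.128, which became 0.0406 after quantile normalization, camera adjusted p = 0.637), led by the collagen prolyl hydroxylase P4ha2 and the oxygen sensor Egln3. Cell proliferation genes fell in 10 of 25 with none rising (12 adjusted over the list alone, median -0.547, camera adjusted p = 0.034 and 0.78), such as the replication clamp Pcna (58.8 ± 14.5 to 37.2 ± 6.77 RPKM), while Mki67 did not pass (8.61 ± 4.27 and 5.90 ± 2.18 RPKM). The median of the proliferation list was -0.242 within replicates 1 to 4 and -1.10 within replicates 5 to 7. With replicates 1 to 4 only, Gpt went from 0.79 to 0.46 (adjusted p = 0.225, over alternatives 0.00114 to 0.225) and Ehhadh from 0.67 to 0.46 (0.0888, 0.000449 to 0.0888), and neither was called. Gpt was not called with the smooth muscle covariate either (0.52, adjusted p = 0.221). The interaction with the replicate sets did not pass for Gpt (adjusted p = 0.439) or Ehhadh (0.427).

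Markers of other cell types moved with the treatment. All 13 smooth muscle genes rose (13 adjusted over the list alone, 12 after quantile normalization, median 0.819, camera adjusted p = 8.55e-10 and 0.26). Their median was 1.03 within replicates 1 to 4 and 0.507 within replicates 5 to 7. The mean smooth muscle score gave an exact p of 0.0286 in the former, the smallest possible. In the latter it gave 0.5, where the smallest possible is 0.1. Myh11 stood at 77.9 ± 34.5 in control and 161 ± 35.7 RPKM in DM-aKG libraries and the actin Acta2 at 124 ± 46.5 and 211 ± 31.7 RPKM. Of 15 fibroblast genes 8 fell and none rose (9 adjusted over the list alone, camera adjusted p = 0.00848 and 0.629). The collagen Col1a1 stood at 55.0 ± 11.9 against 10.4 ± 5.09 RPKM and the secreted glycoprotein Fstl1 at 22.8 ± 2.47 against 11.5 ± 3.28 RPKM. Markers of T and NK cells (0 of 10) and B and plasma cells (0 of 8) gave no call under limma (0 and 1 at an unadjusted p under 0.05), and the lists did not pass (camera adjusted p = 0.108 for the former, 0.0966 for the latter). Antigen presentation genes gave 0 of 15 calls under limma (3 at an unadjusted p under 0.05), while the list passed with a median of 0.308 (camera adjusted p = 0.00025 and 0.629). Red blood cell and adipocyte genes gave 0 of 7 calls each under limma (0 at an unadjusted p under 0.05), while both lists passed, the former with a median of 0.586 (camera adjusted p = 0.0291 and 0.654) and the latter of 0.633 (0.0326 and 0.654). The red blood cell median was 1.59 within replicates 1 to 4 and -1.05 within replicates 5 to 7, the adipocyte median 0.745 and 0.278. Of 20 interferon-stimulated genes 1 fell, Oasl1 (adjusted p = 0.00392), and the list did not pass (camera adjusted p = 0.817).

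In total 735 genes were higher and 3432 lower with DM-aKG among 12433 tested (limma, adjusted p under 0.05), so that 17.6% of the calls were higher. The median log2 change of all tested genes was -0.142, and quantile normalization, which removes such a shift, gave 1750 higher and 1849 lower (48.6% higher), with 22 Wnt target genes still lower. With the smooth muscle score of each library as a covariate 210 were higher and 2291 lower, and 13 of the 65 genes named for this comparison lost their call, among them Lgr5, Myc, Lyz1, Mgam and the defensins. The standard errors of those 4 genes and the defensins rose with the covariate while the changes stayed in the same direction. Lgr5 went from -1.49 (SE 0.38) to -0.96 (SE 0.50, adjusted p = 0.181), Myc from -0.77 (SE 0.21) to -0.64 (SE 0.28, 0.118) and Mgam from 0.53 (SE 0.13) to 0.38 (SE 0.17, 0.117, over alternatives 0.000229 to 0.117). Lyz1 went from 2.17 (SE 0.57) to 1.79 (SE 0.78, 0.109, over alternatives 0.000128 to 0.109) and Defa6 from 5.27 (SE 1.85) to 5.34 (SE 2.57, 0.151). The changes of other defensins shrank. Defa22 went from 3.53 (SE 0.77) to 2.62 (SE 1.02, 0.0768), Defa5 from 3.59 (SE 0.96) to 3 (SE 1.32, 0.116) and AY761184 from 3.82 (SE 0.92) to 2.99 (SE 1.25, 0.0999). Myh11 and Acta2, which are part of that score, were among the 13 as well, with changes of 0.28 (SE 0.13) and 0.09 (SE 0.10) left.

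The control Apc Min against the WT libraries give the change with genotype. It cannot be told apart from the control treatment, because the WT mice are labelled as untreated, or from a cohort or housing difference. Apc Min mice develop adenomas, and the share of adenoma in each library was not measured. The change may therefore include that of adenoma against normal tissue. Here WT values stand first. The genes that fell with DM-aKG were among the largest rises here: Wfdc18, Gkn3, Wif1, Notum, Cfi, Ctse, Clu and Slc38a4 were the 8 leading ones, with Wfdc18 at 0.0754 ± 0.115 in WT and 192 ± 76.5 RPKM in control and Clu at 13.8 ± 9.15 and 705 ± 224 RPKM. Wnt target genes were higher in 21 of 23 and lower in 1, Cdx1 (21 and 2 adjusted over the list alone, median 1.96, camera adjusted p = 1.14e-06 and 0.32). Lef1 was 0.0882 ± 0.0519 in WT and 3.78 ± 1.16 RPKM in control, and Nkd1 3.51 ± 0.599 and 53.2 ± 12.1 RPKM. At the opposite end, genes of antigen presentation were lower in 15 of 15, with Cd74, the invariant chain of class II molecules, at 1351 ± 243 in WT and 94.4 ± 45 RPKM in control.

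Antigen presentation had a median log2 change of -2.48 (15 also adjusted over the list alone, camera adjusted p = 2.94e-18 and 0.153), -2.34 within replicates 1 to 4 and -2.68 within replicates 5 to 7. The class II chain H2-Aa, on chromosome 17 (34282744 to 34287823), was 820 ± 182 in WT against 51.3 ± 26.1 RPKM, H2-Ab1 550 ± 131 against 35.2 ± 18.3 RPKM, and the peptide loading gene H2-DMb1 79.7 ± 17.1 against 4.20 ± 2.24 RPKM. Ubd, an interferon-inducible ubiquitin-like modifier, stood at 67.2 ± 56.4 against 1.27 ± 1.18 RPKM and Upp1, a uridine phosphorylase, at 177 ± 64.8 against 12.4 ± 8.39 RPKM. Of 20 interferon-stimulated genes 19 were lower (20 after quantile normalization, camera adjusted p = 3.37e-14 and 0.181). Ifit1 stood at 15.3 ± 5.47 against 2.35 ± 1.19 RPKM. The 10 T and NK cell genes were all lower (camera adjusted p = 1.2e-11 and 0.153), such as Cd8a (5.36 ± 1.21 against 0.642 ± 0.436 RPKM) and Nkg7, and 7 of 8 B and plasma cell genes were lower (camera adjusted p = 2.75e-05 and 0.268), such as Jchain (497 ± 184 against 69.4 ± 25.9 RPKM) and Mzb1. Myeloid genes went both ways, 5 higher and 7 lower of 17 (5 and 8 adjusted over the list alone, camera adjusted p = 0.0958).

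**Figure D3:**
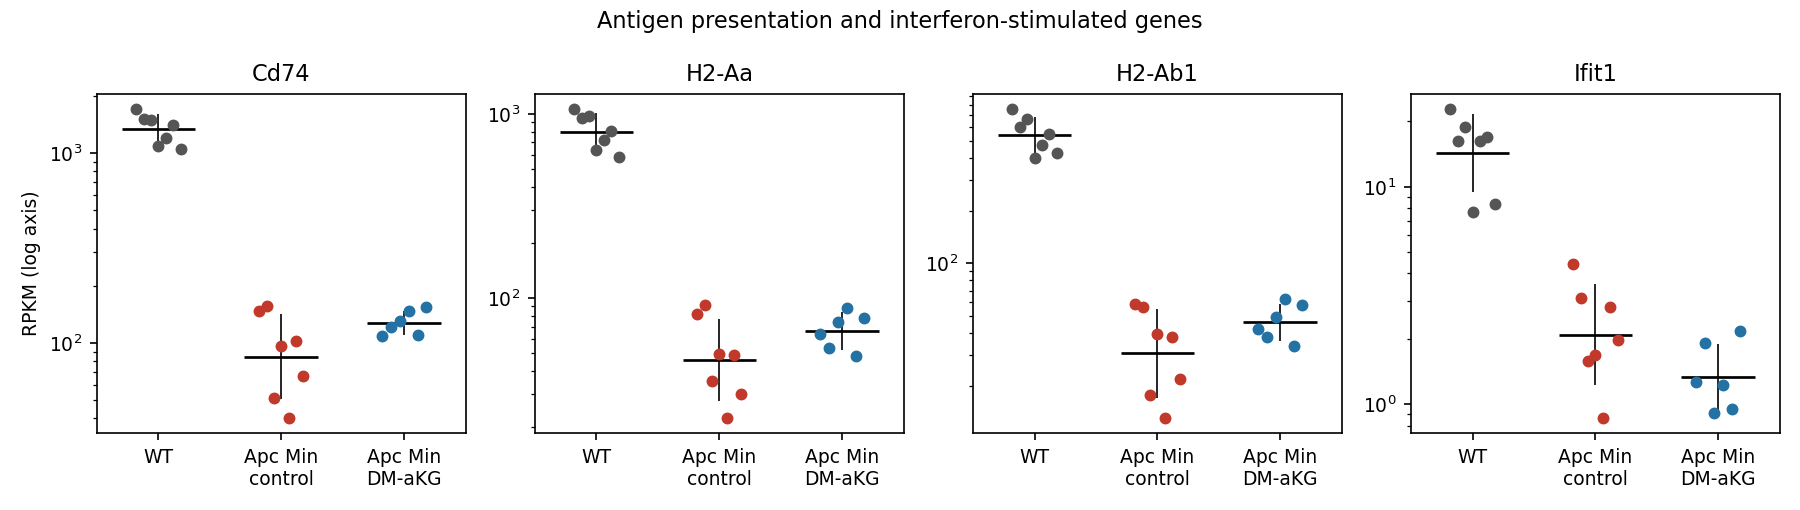
RPKM of Cd74, H2-Aa, H2-Ab1 and Ifit1 in each library on log axes, by group, where each point is a library, the horizontal line the geometric mean and the vertical line 1 SD on the log2 scale. Control and DM-aKG libraries overlap, and both groups lie below the WT libraries for Cd74, whose WT mean was 1351 RPKM.

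Fetal and regenerative genes were higher in 13 of 15 and lower in none (median 1.84, camera adjusted p = 3.55e-05 and 0.32). Anxa3 stood at 3.71 ± 0.677 in WT and 19.998 ± 4.07 RPKM in control and Il1rn at 0.884 ± 0.331 and 23.9 ± 5.69 RPKM. Stem cell genes were higher in 12 of 20 and lower in 2 (camera adjusted p = 0.00919 and 0.707). Lgr5 rose from 2.32 ± 1.19 to 13.5 ± 8.88 RPKM, Axin2 from 13.5 ± 3.75 to 36.5 ± 10.1 RPKM, Myc from 5.36 ± 2.3 to 13.1 ± 3.61 RPKM and Ascl2 from 1.31 ± 0.585 to 2.92 ± 1.17 RPKM, and Olfm4 was lower (78.3 ± 55.4 in WT, 27.2 ± 31.6 RPKM in control, adjusted p = 0.0272). The Olfm4 call was lost without control replicate 1, 3 or 4 or WT replicate 3, 5 or 7 (adjusted p 0.0511 to 0.066, over alternatives 0.0069 to 0.374), and with the smooth muscle covariate (0.374). Of 20 hypoxia-inducible factor targets 15 were higher and 1 lower, the Myc antagonist Mxi1 (camera adjusted p = 0.00146 and 0.32). Slc2a1 stood at 4.804 ± 0.962 against 48.9 ± 16.4 RPKM and the mitophagy gene Bnip3 at 10.7 ± 2.42 against 51.2 ± 11.9 RPKM. In the TCA cycle and glutamine list 20 of 31 were lower and 4 higher (camera adjusted p = 1.18e-07 and 0.153). The glutamine synthetase Glul was higher (26.2 ± 7.88 against 110 ± 36.1 RPKM). Cholesterol synthesis genes were lower in 3 of 23 (0 adjusted over the list alone, median -0.112, camera adjusted p = 0.0101 and 0.707). Over all genes 1948 of 12433 were lower and the median was 0.199, so the list passed against that shift and not by its count of calls.

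Enterocyte genes were lower in 12 of 24 and higher in 1, the apolipoprotein Apoa4 (camera adjusted p = 5.34e-06 and 0.32), including the microvillus protein Vil1 (931 ± 105 against 378 ± 106 RPKM), the glucose transporter Slc5a1 and Krt20 (1251 ± 254 against 530 ± 135 RPKM). Fabp2, which carries fatty acids, was lower (adjusted p = 0.0116) and the lactase Lct, among the 8 leading falls, stood at 83.3 ± 85.4 against 0.846 ± 1.2 RPKM. WT replicates 2 and 4 (0.149 and 0.171 RPKM) lay within the control values for Lct, 0.0169 to 3.17 RPKM. It belongs to the list of the proximal small intestine, of which 4 of 10 were lower and 3 higher (camera adjusted p = 0.397), with a median of -0.0611 within replicates 1 to 4 and -2.62 within replicates 5 to 7. Alpi did not pass (adjusted p = 0.0733). It was called lower without control replicate 2 or 4, DM-aKG replicate 6 or WT replicate 4 (0.0273 to 0.0486) and after median-of-ratios scaling (0.0261, over alternatives 0.0261 to 0.54). Goblet cell genes were lower in 9 of 15 and higher in 2, Retnlb and Galnt12 (2 and 10 adjusted over the list alone, camera adjusted p = 0.00139 and 0.538). Clca1 stood at 746 ± 206 against 144 ± 87.4 RPKM and Muc2 at 369 ± 70.6 against 242 ± 72.6 RPKM. Of 13 Paneth genes 8 were lower and 3 higher (camera adjusted p = 0.103). Lyz1 stood at 1609 ± 1160 against 667 ± 712 RPKM, AY761184 also lower, and Pla2g2a among the higher ones (19.9 ± 9.95 against 296 ± 152 RPKM). The 13 smooth muscle genes were all lower (camera adjusted p = 1.18e-07 and 0.32). The myosin kinase Mylk stood at 130 ± 20.9 against 50.4 ± 19.9 RPKM. Fibroblast genes were higher in 12 of 15 (camera adjusted p = 0.0338 and 0.698). Col1a1 stood at 12.1 ± 2.95 against 55.0 ± 11.9 RPKM and Fstl1 also higher, and endothelial genes in 7 of 12 (camera adjusted p = 0.0171 and 0.698), with Cdh5, the vascular cadherin, and Egfl7. All 7 red blood cell genes were higher (4 after quantile normalization, camera adjusted p = 0.252). The globin Hbb-bs stood at 7.73 ± 4.07 against 40.6 ± 31 RPKM. Alas2, the haem synthesis enzyme of red cells, lost its call after quantile normalization (adjusted p = 0.0674, over alternatives 0.000784 to 0.334). With replicates 1 to 4 only, Alas2 (0.196), Hbb-bs (1.85 to 1.19, adjusted p = 0.242, over alternatives 0.00013 to 0.319) and Fabp2 (-1.37 to -0.65, 0.339, 0.00279 to 0.339) were not called. The smooth muscle covariate ended the calls of Alas2 (0.52, 0.334), Hbb-bs (1.16, 0.319) and Fabp2 (-1.46, 0.109) as well. Chga, Dclk1, Mki67 and Epcam did not pass (adjusted p = 0.172, 0.967, 0.404 and 0.0691). Chga was called lower without WT replicate 4 (adjusted p = 0.0412, over alternatives 0.0412 to 0.509) and after median-of-ratios scaling (0.044). Epcam was called lower without control replicate 4, DM-aKG replicate 5 or WT replicate 7 (0.0284 to 0.0491, over alternatives 0.00221 to 0.305). It was so too after median-of-ratios scaling (0.00221), with the replicate number as a block (0.0199) and with the replicate sets as a factor (0.0163).

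In this comparison 5368 genes were higher and 1948 lower in control Apc Min than in WT (limma), 73.4% of calls being higher, with a median log2 change over all genes of 0.199. Quantile normalization gave 3239 higher and 3348 lower (49.2% higher). Apc was 10.2 ± 2.28 in WT and 14.5 ± 4.1 RPKM in control (log2 change 0.45 ± 0.16 SE, adjusted p = 0.021). That call was lost after quantile normalization (0.146, over alternatives 0.00339 to 0.421) or median-of-ratios scaling (0.205), with replicates 1 to 4 only (0.272), with the smooth muscle covariate (0.421), without control replicate 5 (0.0534) and without WT replicate 1 (0.0539). With the smooth muscle score as a covariate 3016 were higher and 600 lower, and 10 named genes lost their call. Their standard errors rose here too. Lgr5 went from 1.96 (SE 0.37) to 1.35 (SE 0.53, adjusted p = 0.0613, over alternatives 3.13e-05 to 0.0613) and Ascl2 from 0.75 (SE 0.19) to 0.69 (SE 0.29, 0.0774, 0.00049 to 0.0774). AY761184 went from -3.95 (SE 0.89) to -2.98 (SE 1.32, 0.0978, 6e-06 to 0.0978). Muc2 went from -0.64 (SE 0.18) to -0.46 (SE 0.27, 0.208, 0.000263 to 0.208) and Lyz1 from -1.54 (SE 0.54) to -1.11 (SE 0.82, 0.327, 0.00146 to 0.327).

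The treated Apc Min against the WT libraries show what differed from WT under DM-aKG, whose values stand first here. This comparison joins the treatment with the genotype, and a cohort or housing difference cannot be told apart from them. Antigen presentation was lower in all 15 genes (median -2.32, camera adjusted p = 5.77e-17 and 0.157), with Cd74, on chromosome 18 (60803848 to 60812652), at 129 ± 18.8 in DM-aKG and 1351 ± 243 RPKM in WT and H2-Aa at 67.6 ± 15.3 and 820 ± 182 RPKM. Wnt target genes were higher in 6 of 23 and lower in 1, the cell cycle gene Ccnd1 (7.99 ± 3.12 against 30.1 ± 7.17 RPKM), and the list did not pass (camera adjusted p = 0.192). Notum (8.75 ± 13.7 against 0.128 ± 0.0459 RPKM), Wif1 and Clu (76.4 ± 80.9 against 13.8 ± 9.15 RPKM) were higher than in WT on average. DM-aKG replicate 2 raised these means, and without it the log2 change went from 2.09 to 1.499 for Notum (adjusted p = 0.0103), from 2.06 to 1.54 for Wif1 (0.00964) and from 2.02 to 1.59 for Clu (0.00204). Not every treated library lay above WT: Wif1 was 0.116 and 0.275 RPKM in DM-aKG replicates 1 and 6, within the WT values of 0.0682 to 0.312 RPKM, and Clu was 17.7 and 28.2 RPKM in the same libraries against 34.3 RPKM in WT replicate 1. Among the largest rises over WT were Pdk4, the kinase that shuts off pyruvate dehydrogenase, on chromosome 6 (5483351 to 5496309), at 127 ± 124 against 1.58 ± 0.414 RPKM and G6pc, the last enzyme of glucose release, at 61.8 ± 65 against 1.94 ± 0.828 RPKM. DM-aKG replicate 5 raised the G6pc mean, at 192 RPKM against 19.3 to 52.9 RPKM in the other DM-aKG libraries.

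Other leading rises were the sulfotransferase Gal3st2b, the metallothionein Mt2 (186 ± 108 against 16.4 ± 8 RPKM), Rab30, the thiolase Acaa1b and Tmem37, by 2.82 to 3.88 on the log2 scale. The means of these genes, and of Pdk4 and G6pc, were above WT in control Apc Min libraries too. In control, Mt2 stood at 224 ± 129, Pdk4 at 51.2 ± 51.0 and G6pc at 40.6 ± 39.4 RPKM. Fatty acid oxidation genes were higher in 11 of 21 and lower in none (12 adjusted over the list alone, camera adjusted p = 0.000367 and 0.592). In control Apc Min libraries 10 of them were already higher than in WT and 3 lower (median 0.587, camera adjusted p = 0.947). The nuclear receptor Ppara stood at 29.6 ± 13.4 against 5.45 ± 0.937 RPKM and the mitochondrial thiolase Acaa2 at 80.3 ± 32 against 32.0 ± 3.82 RPKM. Interferon-stimulated genes were lower in 19 of 20 (20 adjusted over the list alone, camera adjusted p = 1.54e-16 and 0.157). Ifit1 stood at 1.41 ± 0.517 RPKM. Also among the 8 leading falls were Ubd, Upp1, H2-DMb1, H2-Ab1, the tryptophan-degrading Ido1 (2.82 ± 1.65 against 43.2 ± 16.7 RPKM) and the granzyme Gzma (6.28 ± 3.15 against 73.7 ± 26.5 RPKM). All 10 T and NK cell genes, Cd8a among them, were lower (camera adjusted p = 9.02e-12 and 0.157), and 7 of 8 B and plasma cell genes (camera adjusted p = 0.000237 and 0.416). Jchain stood at 121 ± 53.1 RPKM. Cholesterol synthesis was lower in 16 of 23 (18 adjusted over the list alone, camera adjusted p = 3.55e-07 and 0.583). The squalene epoxidase Sqle stood at 23.3 ± 5.5 against 68.5 ± 26.9 RPKM and Fdps also lower. Proliferation genes were lower in 16 of 25 (19 adjusted over the list alone, camera adjusted p = 9.06e-06 and 0.626). The apoptosis inhibitor Birc5 stood at 2.68 ± 0.929 against 6.12 ± 0.827 RPKM and the mitotic kinase Aurka at 2.503 ± 0.765 against 5.34 ± 1.27 RPKM. The median of the proliferation list was -0.248 within replicates 1 to 4 and -1.32 within replicates 5 to 7. Mki67 did not pass (adjusted p = 0.0797). Of the alternatives (0.00998 to 0.798) it passed without WT replicate 1 (0.0375) and under quantile normalization (0.0455), median-of-ratios scaling (0.0406) and array weights (0.00998).

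Goblet cell genes were lower in 8 of 15 and higher in 1, Retnlb (1 and 9 adjusted over the list alone, camera adjusted p = 0.00149 and 0.592). Muc2 stood at 213 ± 37 against 369 ± 70.6 RPKM and the kallikrein Klk1 at 16.3 ± 5.22 against 55.8 ± 18.3 RPKM. Enterocyte genes were higher in 5 and lower in 4 of 24 (camera adjusted p = 0.418), Krt20 lying at 456 ± 167 against 1251 ± 254 RPKM. Enteroendocrine genes were higher in 7 of 14 (camera adjusted p = 0.00814 and 0.498), among them the hormone Pyy (56.2 ± 16.4 against 19.9 ± 8.5 RPKM) and the neuroendocrine chaperone Scg5. In the TCA cycle and glutamine list 16 of 31 were lower and 2 higher (16 and 4 adjusted over the list alone, camera adjusted p = 0.00212 and 0.498). The citrate synthase Cs stood at 176 ± 35.6 against 322 ± 50.3 RPKM and Glul higher at 94.0 ± 27.8 against 26.2 ± 7.88 RPKM. Endothelial genes were higher in 11 of 12 (12 adjusted over the list alone, camera adjusted p = 4.65e-06 and 0.416), such as Egfl7 and the adhesion molecule Pecam1, and red blood cell genes in 7 of 7 (camera adjusted p = 0.00212 and 0.592), Hbb-bs lying at 50.9 ± 37.6 against 7.73 ± 4.07 RPKM. Smooth muscle genes gave 0 calls of 13 under limma (1 at an unadjusted p under 0.05, camera adjusted p = 0.391). Lgr5, Axin2, Ascl2, Myc, Olfm4, Lyz1, Fabp2, Alpi, Chga, Dclk1 and Apc did not pass, with adjusted p from 0.0505 for Apc to 0.865 for Dclk1. Pan-epithelial genes were lower in 4 of 15 (camera adjusted p = 0.0167 and 0.592). Epcam was lower (654 ± 77.3 against 937 ± 109 RPKM, adjusted p = 0.00117, over alternatives 6.43e-05 to 0.0542, the highest after quantile normalization). Apc was called higher in 11 alternatives (over alternatives 0.0125 to 0.122). These were leaving out control 1, 4 or 5, DM-aKG 4 or WT 4 or 5 (adjusted p 0.0258 to 0.0489), a threshold of 5 RPKM (0.0486), a pseudocount of 0.1 (0.0484), only the 2 groups compared (0.018), the replicate number as a block (0.0182) and the replicate sets as a factor (0.0125). Axin2 was called lower in 5: without DM-aKG 2 or WT 1 (0.018 and 0.0293), with array weights (0.00584), after median-of-ratios scaling (0.0481) and with the smooth muscle covariate (0.0433, over alternatives 0.00584 to 0.588). Myc was called higher without WT 5 (0.0325) and with the replicate number as a block (0.0494, over alternatives 0.0146 to 0.244), and Chga without DM-aKG 6 (0.0457, over alternatives 0.0457 to 0.282). With replicates 1 to 4 only, Lyz1 was called higher than in WT (0.63 to 1.59, adjusted p = 0.00639, over alternatives 0.00639 to 0.657), Myc was called higher (0.0146) and Aurka was not called (-0.86 to -0.61, 0.0906, 0.000186 to 0.0906). The median of the Paneth list was 1.71 within replicates 1 to 4 and -0.77 within replicates 5 to 7. In total 2722 genes were higher and 2151 lower than in WT (55.9% higher), and median-of-ratios scaling gave 2251 higher and 2787 lower (44.7% higher), so the direction of the majority depends on the scaling.

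Whether DM-aKG moved the genes of the genotype comparison toward WT was asked across genes, which are not independent replicates. Over the 7316 genes called between control Apc Min and WT, the log2 change with DM-aKG correlated with the log2 difference of WT over control at r = 0.742, and 83.2% of these genes moved toward WT. Both changes use the same control libraries. Groups simulated with no change by treatment or by genotype gave r = 0.478 on average (-0.00416 to 0.851 over 100 draws). In them 66.5% moved toward WT (47.1 to 83.6%), and both ranges hold the observed values. The simulation removes the genotype difference as well. It therefore cannot show what r or percentage the shared controls alone would give with that difference kept. Splitting the controls between both changes gave r from 0.457 to 0.836 and 68.4 to 90.9% over 70 splits. The covariance, 0.373, lay above the simulated one (0.0171 on average, -0.000433 to 0.0481), a difference of 0.356. Of the 5368 genes higher in control Apc Min than in WT, 2587 were called lower with DM-aKG, a count that the shared controls also raise, and 2267 were still called higher in DM-aKG libraries than in WT. Of the 1948 genes lower in control Apc Min, 386 were called higher with DM-aKG and 1204 were still called lower than in WT.

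**Figure D4:**
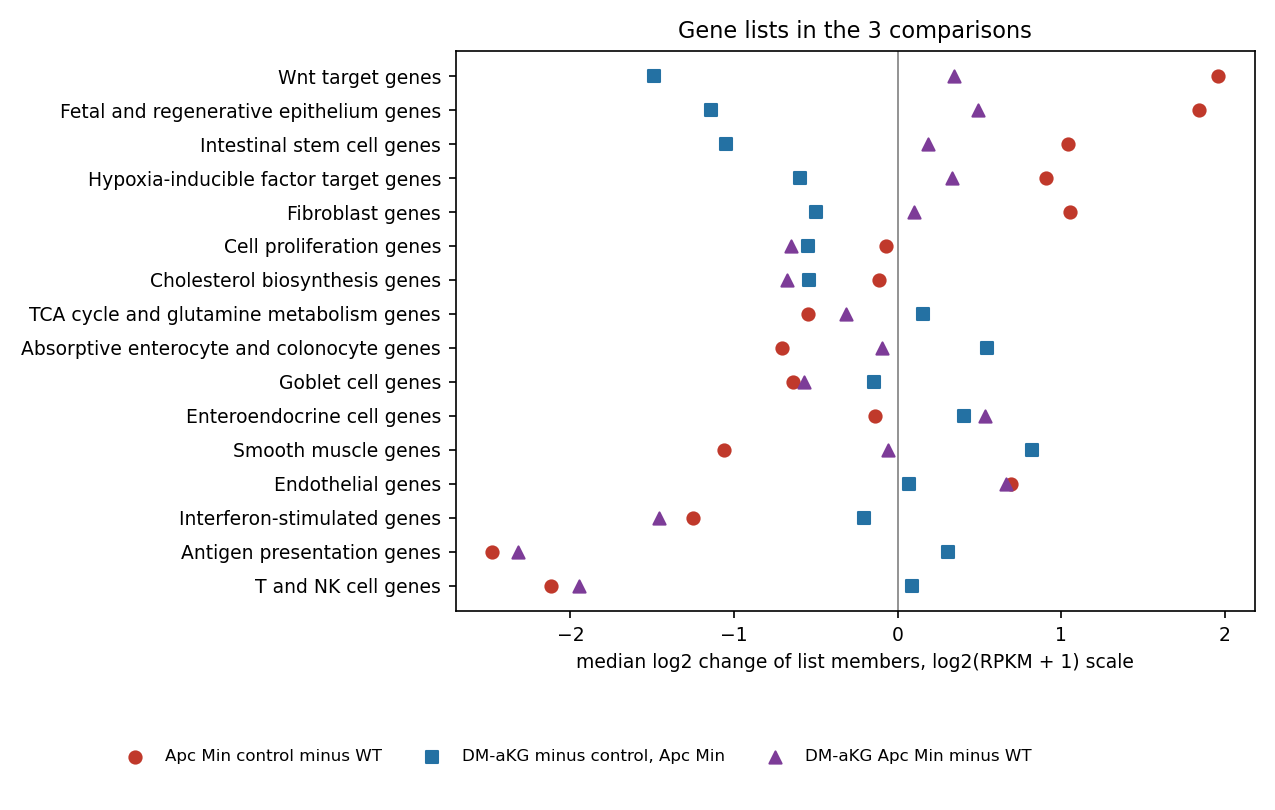
Median log2 change of the members of 16 gene lists, on the log2(RPKM + 1) scale, in the 3 comparisons, where a circle is control Apc Min minus WT, a square DM-aKG minus control and a triangle DM-aKG Apc Min minus WT. The Wnt target medians are 1.96, -1.49 and 0.345, and the antigen presentation medians -2.48, 0.308 and -2.32, in that order.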

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

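The tests chosen only after the result was seen were those of the epithelial share, of a mixture with WT-like tissue and of dilution for the Wnt pattern, those of myeloid cells, of lymphocytes and of tumour tissue for the antigen presentation pattern, and the division of replicates into 1 to 4 and 5 to 7. Among 447 sets of values, each a single measure in a single group of libraries, 50 had a library far from the others. In each case the gap from that library to its nearest neighbour was large against the range of its group. Chance gives about 1 in 20 for independent, normally distributed values. RPKM of genes that move together are not such values, so the count of 50 cannot be set against that rate.

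The DM-aKG library of replicate 2 stood highest of the 6 in 17 measures, most of them genes that fell with treatment: Notum 35.94, Axin2 18.26, Lgr5 8.932, Nkd1 27.3, Tnfrsf19 4.64, Mex3a 1.694, Clu 234.7, Wfdc18 41.58, Ctse 54.43, Gkn3 19.79, Cfi 33.34, Slc38a4 26.22, Pla2g2a 216.9, Slc2a1 31.87, Lcn2 74.48, Cldn4 82.48 and Scg5 3.895 RPKM. Its Notum lay above the 7.394 RPKM of the next DM-aKG library and below the lowest control library at 41.1 RPKM. The DM-aKG library of replicate 5 stood apart in 8 genes, highest for the fat oxidation and fasting genes G6pc (191.6 RPKM), Ehhadh (43.8), Acaa1b (56.72), Ppara (55.4), and for Gal3st2b (62.2) and Slc26a3 (85.44), and lowest for Epcam (506.5) and Birc5 (0.8957).

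The control library of replicate 1 was highest for Sst (28.72 RPKM), Pycr1 (8.085), Acaa1b (40.2), Tmem37 (104.8) and Pyy (96.02), and lowest in depth (21.3 M reads) and in the mean log2 value of the fetal and regenerative list (4.102). Control replicate 4 was highest for Krt20 (807.6), Epcam (978.2) and Col1a1 (78.8), and control replicate 6 for AY761184 (461.3) and Duoxa2 (69.39). DM-aKG replicate 4 was highest for Dclk1 (2.36 RPKM) and the tuft cell list (mean log2 value 2.667). DM-aKG replicate 6 was highest for Fabp2 (6925) and for Lct (194.6, the next library lying at 1.847 RPKM), and lowest for Pyy (25.55). Among WT libraries, replicate 1 was highest for Stra6 (0.653) and Clu (34.27), replicate 2 for Wfdc18 (0.3259) and Pyy (37.79), replicate 5 for Mex3a (0.3575) and Pla2g2a (40.49), and replicate 6 for Bpifb5 (0.02081), while replicate 4 was lowest for the enteroendocrine list (mean log2 value 2.959).

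The effect of DM-aKG differed between replicates 1 to 4 and 5 to 7 in 26 genes by an interaction term in limma (1460 at an unadjusted p under 0.05), among them the Paneth genes Defa5, Defa22, Defa3, Defa17, Defa24 and Ang4. For both comparisons with WT limma called 0 genes, with 439 and 786 at an unadjusted p under 0.05.

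Chance division of the libraries was weighed with 100 splits of each pair of groups, the real one included and the others drawn at random. The splits take libraries as separate units, while the labels do not say which came from separate animals. Within that limit the counts argue against a chance division. With DM-aKG 4167 genes were called and 1 of 100 splits, the real one, reached that, the highest other split giving 1732. Control Apc Min against WT gave 7316 (1 of 100, highest other 2556), and DM-aKG Apc Min against WT 4873 (1 of 100, highest other 2489).

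For the fall of Wnt target genes with DM-aKG (median -1.49), the values argue against a lower share of epithelial cells alone, since the pan-epithelial list had a median of -0.293. The SE of that list over its members was 0.18, which measures the spread between genes and not between libraries. Scaling alone is excluded too, as 22 Wnt target genes were lower after quantile normalization. Treated libraries made of control-like and WT-like tissue would carry WT antigen presentation levels in proportion. The observed level was 0.163 of the expected one (0.0987 to 0.239 per library). The control share, 0.105, was set by 24 genes at 10 RPKM or more in control and under 0.5 RPKM in WT libraries. Antigen presentation genes were chosen after they were seen to be low in both Apc Min groups, so a low ratio was to be foreseen. It cannot show how much normal tissue a treated library held. A smaller share of Apc-mutant cells diluted by Apc Min tissue that no library measures alone cannot be told apart from lower Wnt signalling per cell: 23 of those 24 genes were lower, with ratios spread by an SD of 1.05 against a median SE of 0.334 for 1 gene, and the diluting tissue may express some of them. An action of DM-aKG on the pathway stays open beside it.

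Antigen presentation genes were low in both Apc Min groups (median -2.48 in control). Fewer myeloid cells of every type alike would lower myeloid genes as much, but their median was -0.28 (SE over list members 0.244). Myeloid genes went both ways, so this median cannot speak to the loss of a single myeloid cell type. Fewer lymphocytes cannot be told apart from lower expression per cell, since 2 lymphocyte lists fell too. The B and plasma cell list had a median of -1.3 (SE over list members 0.299) and the T and NK cell list of -2.12 (SE over list members 0.285). Tumour tissue taking the place of other tissue cannot be judged from these values. It would let the genes return where tumour is less, but low Wnt targets need not mean less tumour. The median in DM-aKG libraries against WT was -2.32, and their highest library median log2 value (5.43) lay below the lowest of WT (6.33). That low level is part of the pattern itself, seen before the test was chosen. A cohort, housing or vehicle difference between WT and Apc Min animals cannot be told apart from the genotype, since the design joins them. Of 16 interferon-inducible genes on no fixed list, 15 were lower in both Apc Min groups, which may follow from either.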

How the results depend on the processing

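All settings were chosen before the data were examined except median-of-ratios scaling, replicates 1 to 4 only, the 2 sets of replicates as a factor and the smooth muscle covariate, which were added after seeing the data. Settings for counts (DESeq2 size factors, library totals and the DESeq2 test) were not run, since the values are RPKM. Counts are given as higher and lower, against 735 and 3432 for DM-aKG over control, 5368 and 1948 for control Apc Min over WT and 2722 and 2151 for DM-aKG Apc Min over WT. Adding a log2 change of at least 1 left 49 and 495, 905 and 458, and 294 and 306, by construction. Quantile normalization gave 1750 and 1849, then 3239 and 3348, and median-of-ratios scaling 1367 and 1815, then 3258 and 3412; both remove the shift of the median gene, which was -0.142 and 0.199. At least 5 RPKM, which tests fewer genes, gave 459 and 2212, then 3306 higher for genotype and 1712 higher for DM-aKG over WT. Replicates 1 to 4 only, with fewer libraries, gave 378 and 1613 for DM-aKG and 1432 lower for DM-aKG over WT. The smooth muscle covariate gave 210 higher for DM-aKG and 3016 and 600 for genotype. All smooth muscle genes were called in both of those comparisons, so the score goes partly with the groups and takes up part of the contrast. For DM-aKG over WT, where no smooth muscle gene was called, it gave 2647 and 2025. What lay behind the lost calls was not tested. Leaving out 1 library gave 571 to 880 and 2866 to 3690 for DM-aKG, 4985 to 5474 and 1695 to 2024 for genotype, and 2217 to 2970 and 1570 to 2265 for DM-aKG over WT. For named genes with 1 library left out, 1279 results for DM-aKG kept their side of the threshold, 19 lost a call and 2 gained one, against 1064, 8 and 8 for genotype and 1009, 0 and 11 for DM-aKG over WT, with 0 reversed. Calls shared in the same direction with quantile normalization numbered 2553, 5088 and 4159. Lists passing camera fell from 17, 15 and 13 to 0 in each comparison with an estimated correlation, and fry called 24 for genotype. The NRF2 list, not called by camera for genotype (adjusted p = 0.947), was called up by fry (4.84e-05). Camera compares the test statistics of its members with those of other genes, and fry tests them against no change. The median log2 change of the list was 0.188. Camera made no call, so no called direction turned. The lowest correlation over splits of the controls was 0.457. With the replicate number as a block the counts were 758 and 3603, 5675 and 2084, and 3151 and 2335, and of 19 same-numbered pairs 8 correlated over 0.1, 4 of 20 libraries correlating best with their own number, so the numbers were not taken to pair the libraries. Depth, 21.3 to 29.3 M reads, limits genes near 1 RPKM.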

Other observations

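The test of glucocorticoid-induced and clock genes was chosen after genes of fasting and stress were seen to be high in both Apc Min groups. Its bounds were set before its own result was seen, but did not take in the error of the clock medians, which was weighed as well. The gene lists described first were fixed in advance. Enteric neuron and glia genes passed camera with DM-aKG (adjusted p = 0.00221, adjusted p = 0.26 with an estimated correlation), 3 of 8 rising (4 adjusted over the list alone) and 1 falling, the receptor Ret (adjusted p = 2.29e-05), which was also higher in control Apc Min than in WT (adjusted p = 2.61e-09). BMP and TGF-beta pathway genes fell in 11 of 19 with none rising (camera adjusted p = 0.058). Among myeloid genes, those higher in control Apc Min than in WT were the neutrophil genes S100a8 and S100a9, the macrophage receptors Mrc1 and Cd163, and Cd14. Onecut2, a transcription factor of the duodenum, was at 12.651 RPKM in control, 0.92653 in DM-aKG and 0.14998 in WT libraries on average (log2 change 3.52 over WT, adjusted p = 1.1e-09). Ret, Onecut2 and these myeloid genes were chosen after their values were seen.

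Pdk4, Ddit4, Glul, Mt2 and G6pc were high in both Apc Min groups against WT. A glucocorticoid response is a candidate explanation: of 7 glucocorticoid-induced genes outside this set, 6 were called higher in both Apc Min groups, with Fkbp5 at 53.3 ± 18.2 in control (n = 7), 73.3 ± 33.2 in DM-aKG (n = 6) and 10.2 ± 6.84 RPKM in WT libraries (n = 7), and Tsc22d3 was called only in DM-aKG libraries (adjusted p = 0.0143). Another time of day at collection stays open. The medians of clock output and core clock genes differed by -0.182 (SE over list members 0.456). This difference lay within the bound set in advance against that explanation. That bound took no account of the error, and the spread is too wide to decide. Of the 9 genes Dbp was lower in control Apc Min than in WT (-1.38, adjusted p = 7.49e-06), Nfil3 (1.41, 2.01e-05) and Cry1 (0.37, 0.0158) were higher and 6 did not pass. Fasting, handling and vehicle were not tested and go with the same groups.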
